A study of Arabidopsis thaliana with 28 samples.

How the data were processed

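RNA from entire aerial parts was extracted with an RNeasy kit, amplified and labelled with biotin by a MessageAmp kit and hybridised to 1-colour arrays, per the labels' protocols. The values used here are the log2 signals deposited by the authors in the series' value table, 1 column per array. GCRMA and limma are named for them per the submitters' processing notes, without versions or the role of each. The table's range and floor fit log2 values, and the centring between arrays is not given in the sources used here. Signals near the floor of 2.13 carry little information on differences, and a fold change against such a signal depends on the floor. The probe-level signals were not used here.

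The table holds 22810 probe sets. The 64 array control probe sets were left out of the comparisons, leaving 22746. The platform annotation used here gives 1 gene for 13513 probe sets, several for 503 and no name for 8730, and only those with 1 gene were named. Symbols were updated from the RefSeq gene table of the organism, in which 13436 of those 13513 probe sets matched a locus, and its coordinates were not used because the files name no genome build. A gene with more than 1 such probe set was measured by the one of highest mean over all arrays. Of the 11 overexpressed factors, 1 (ZAT10) was named on the array, so the transgene could be checked only there.

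Groups were taken from the sample labels. The titles of the MYB44 and MYB73 arrays read MYB4 and MYB7, and the source names, which give MYB44 and MYB73, were followed. Neither transgene could be checked on the array. Probe sets entered the tests where their log2 value was over 4 in at least 2 of the 28 arrays, which kept 15916. Group means of all 28 arrays were fitted together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 14 residual degrees of freedom, and p-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05 and no fold threshold. The comparisons were cold against WT of the same experiment, each line against the WT labelled as the lines' control, and the WT groups against each other. The comparison of CZF1 with the WT of the cold experiment was planned as an alternative and was brought forward as a comparison of its own after the array medians had been seen.

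The named genes follow a rule set before the data were examined. From probe sets of 1 gene past the threshold, with every array of one group beyond every array of the other, it takes the 10 largest rises and falls for the cold and the 5 largest of each for a line. It also takes COR15A and COR47 (CBF1, CBF2, CBF3, RD29A and GOLS3, also in the rule, are unnamed here), the transgene, and up to 4 members past the threshold of each gene list called, and any list member may be given as a value. ZAT10 outside its own line, COR15B and LTI30 outside called lists, and the unnamed probe sets were added after values were seen.

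Gene lists were tested with limma's camera (preset correlation 0.01), adjusted over 325 tests of 25 lists in 13 comparisons. Of the 20 lists written before the data were examined, with 211 genes, 26 genes were named on the array and 3 lists had at least 3 measured members. These were CBF regulon genes, flavonoid and anthocyanin synthesis, and root tissue markers. Another 22 lists were made from the annotation's names once the table had been seen and before any comparison between groups. Of the 325 tests 29 passed, 0 of them passed limma's camera with an estimated correlation, and 10 passed with fry, which asks whether a list's genes move one way on balance and does not compare them with other genes. The root tissue markers passed in 0 comparisons in camera, with adjusted p from 0.164 in MYB44 and RAV1 to 0.951 in the cold.

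Overlaps between calls used Fisher's exact test (two-sided), adjusted over all lines and directions. Covariances between comparisons sharing arrays were set beside those of unchanged groups in 100 simulations, with the spread pooled over all groups. The root mean square SD was 0.707 in CRF3, 0.181 in the lines' control and 0.246 in the WT of the cold experiment. The simulated covariances may therefore be too high for those WT arrays. Overlaps were set beside those of independent lists. In 50 simulations 2 unchanged groups with the same control arrays shared 0 calls by limma, but unchanged groups had 0.06 calls on average. With almost no calls to share, this does not measure how far shared controls raise the overlap of lines with many calls. The steps were tested on simulated data with changes added to the real means. In the cold comparison 45% of probe sets changed by 1 and 94% of those changed by 2 on the log2 scale were recovered, with 13 false calls among 15916 probe sets, and in HSFC1 50% and 92% with 6 false calls.

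The alternatives planned were a fit of only the groups compared, no filter, a filter at 6, quantile normalization, a trended and robust prior, the replicate number as a block, a 2-fold threshold, leaving out each array in turn, the other WT group or all 4 WT arrays as control, camera with an estimated correlation and fry. A fit whose spread came from the groups other than CRF3, the overlap and covariance of CRF3 without each of its replicates, and CZF1 against the WT of the cold experiment without each array, were added after seeing the data. When 1 array was left out, the lone array of a group was assumed to vary like those of the other groups.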

Results

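Transcript levels were measured on 28 single-colour oligonucleotide arrays with RNA from the entire aerial parts of Arabidopsis thaliana Col-0 seedlings grown for 12 days at 22°C under constant light of about 100 µmol per square metre per second. The arrays fell into 14 groups of 2. Wild type (WT) at 22°C and WT held at 4°C for 24 h formed a cold experiment, and the cold plants were also kept at a lower light of about 30 µmol, so temperature and light changed together. The other groups were 11 lines, each overexpressing a transcription factor that the series describes as induced by cold (CRF2, CRF3, CZF1, DEAR1, ERF5, HSFC1, MYB44, MYB73, RAV1, ZAT10 and a zinc finger factor labelled ZF), and a second WT group at 22°C labelled as their control. The word biological in the replicate labels is the only statement of where the replicates came from. The p-values rest on the spread between arrays within groups, whatever its origin. That spread was pooled over all 14 groups for each probe set, so it is not that of the groups compared alone. With 2 arrays per group, the number of arrays limits the precision of every value. Values are log2 signals from 2.13 to 14.94, levels are given as mean ± SD (n = 2 arrays), and changes as log2 differences ± SE with limma's adjusted p. Both arrays of a group lay beyond both arrays of the other for each gene named as among the largest rises or falls.

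The first question was which genes changed in WT during 24 h at 4°C. COR15A (AT2G42540), whose product protects chloroplast membranes during freezing, rose from 8.59 ± 0.21 to 14.17 ± 0.03, a change of 5.58 ± 0.45 (adjusted p = 6.1e-08). The dehydrin LTI30 (AT3G50970) rose by 5.60 ± 0.45 (adjusted p = 5.61e-08), COR15B (AT2G42530) by 4.45 ± 0.47 (adjusted p = 1.77e-06) and the dehydrin COR47 (AT1G20440) by 3.87 ± 0.57 (adjusted p = 6.23e-05). COR27 (AT5G42900), a regulator of the circadian clock, rose by 4.18 ± 0.42 (adjusted p = 8.65e-07). The largest rise among probe sets naming 1 gene was that of AT1G16850, from 4.54 ± 0.19 to 11.63 ± 0.01. AT1G51090, AT4G33905, AT4G30830, AT2G16890 and AT3G55580 rose by 5.60, 4.96, 4.43, 4.09 and 3.96.

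Among the falls, AT1G13650 went from 7.35 ± 0.64 to 2.13 ± 0.00, the lowest value of the whole data set, so that its change of -5.22 is set by that floor. EXPA8 (AT2G40610), an expansin that loosens cell walls, fell by 4.03 (SE 0.61, adjusted p = 8.18e-05). AT2G34620, AT3G26510, AT4G27450, AT4G21870, AT4G33666, AT3G23080, AT1G53560 and AT3G47560 changed by -4.23, -4.21, -4.17, -4.15, -3.92, -3.80, -3.71 and -3.59. ZAT10 (annotated as STZ, AT1G27730), the one overexpressed factor whose probe set the annotation names, changed by 2.08 ± 0.70 (adjusted p = 0.0344), and this call was lost when any 1 of the 4 arrays was left out (adjusted p 0.0778 to 0.173), without the filter on signal, and after quantile normalization.

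All 4 measured members of the fixed list of CBF regulon genes (LTI30, COR15A, COR15B and COR47) rose, also when adjusted over the list alone, with a median change of 5.02 (camera adjusted p = 2.17e-05, and adjusted p = 0.551 with an estimated correlation). Of 6 late embryogenesis abundant proteins, 5 rose and 0 fell (limma adjusted p), these being the same 4 genes and LEA4-5 (AT5G06760), which went from the floor of 2.13 to 4.49. The list's camera adjusted p was 9.55e-06, and its adjusted p = 0.551 with an estimated correlation. Of 32 nuclear photosynthesis genes 9 fell, with a list median of -0.65 (camera adjusted p = 0.00113, and adjusted p = 0.893 with an estimated correlation). They included PGRL1B of cyclic electron flow (-1.98 ± 0.32, adjusted p = 0.000161), the minor antenna protein LHCB4.2 (-1.98 ± 0.47, adjusted p = 0.00434), and HEME1 and CHLM of tetrapyrrole synthesis (-1.77 and -1.43). Of 66 chloroplast-encoded genes 8 fell and 1 rose, with a median of -0.54 (camera adjusted p = 0.0095, and adjusted p = 0.918 with an estimated correlation), among them rpl16 (-1.58), rpoC2 (-1.54) and rps18 (-1.15), while petD rose by 0.73. The count of 8 of 66 does not set this list apart, since 2091 of all 15916 tested probe sets fell, a share no lower. With all 4 WT arrays at 22°C as control, rpoC2 and rps18 lost their calls. Over all 15916 probe sets tested, 2238 rose and 2091 fell, of which 2340 changed at least 2-fold. The share higher was 51.7%, and 68.8% with all 4 WT arrays at 22°C as control (4345 higher and 1967 lower). Whichever array was left out, 24 of the 30 named genes past the threshold kept their call, and ZAT10 did not. CHLM and rpoC2 lost theirs without replicate 1 of either group (adjusted p up to 0.0817 and 0.0872), rps18 without replicate 2 of either group (adjusted p up to 0.14) and LHCB4.2 without cold replicate 1 (adjusted p = 0.0572). Leaving out 1 array gave 2838 or 2863 changed probe sets without WT replicate 1 or 2, and 2799 or 2839 without cold replicate 1 or 2.

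**Figure D1:**
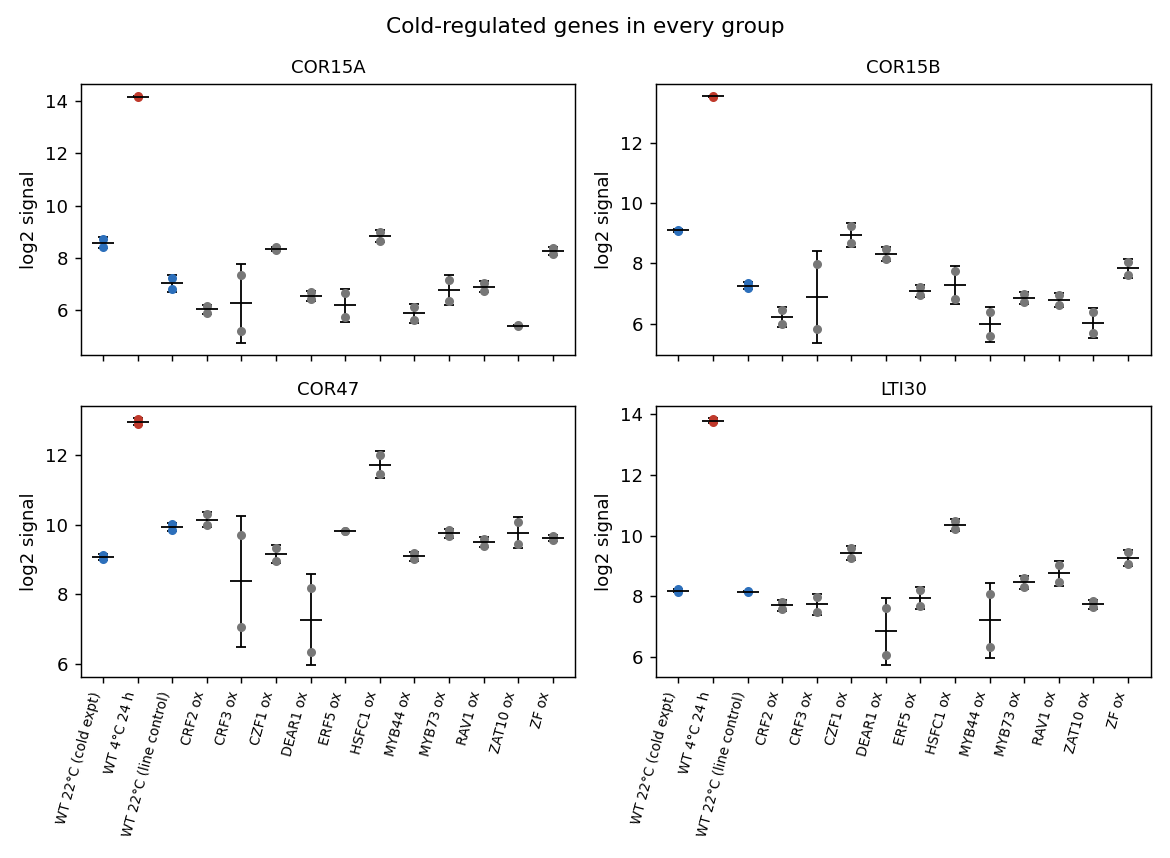
Log2 signal (vertical axis) of cold-regulated genes in each of the 14 groups (horizontal axis), with points for arrays (WT at 22°C blue, WT at 4°C red, lines grey), horizontal marks for group means and error bars for the SD. COR15A stood at 14.17 in the cold against 8.59 in its WT, and at 8.84 in HSFC1 against 7.04 in the WT control of the lines.

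For the lines, the question was how the transcript profile of each overexpressor differed from that of WT. In signs of RNA quality, the difference between 3' and 5' GAPDH probe sets was 0.75 and 0.91 in the 2 control arrays. It was higher in both arrays of 10 of the 11 lines, but also in the WT of the cold experiment (1.11 and 1.83). That of ubiquitin was 1.27 and 1.2 in the control and higher in both arrays of 8 lines, and that of actin in 3. Of 12 groups, 0 had both arrays above all 4 WT arrays at 22°C in GAPDH or actin, and 7 in ubiquitin. In the line overexpressing HSFC1, a class C heat stress transcription factor, genes of small heat shock proteins were among the largest rises. ATHSP22.0 (AT4G10250), a small heat shock protein of the endoplasmic reticulum, went from 2.14 ± 0.01 to 9.46 ± 0.61 (change 7.32 ± 0.20, adjusted p = 2.89e-15). AT1G53540, of the cytosolic small heat shock proteins, went from 2.14 ± 0.00 to 9.90 ± 1.29 (adjusted p = 3.07e-12), and AT2G29500, of the same family, from 2.89 ± 0.10 to 10.18 ± 0.40 (adjusted p = 5.56e-12). AT1G52560 rose by 8.41 ± 0.31 and AT5G07330 by 8.09 ± 0.27 (adjusted p = 5.06e-13 and 8.48e-14). The control values of these 5 genes lay at or near the floor of 2.13, so their changes depend on that floor. AT1G66100, a thionin, AT1G67865, AT1G73600, AT1G31690 and AT3G28220 changed by -4.37, -4.01, -3.96, -3.94 and -3.85, with adjusted p from 6.52e-05 in AT1G67865 to 0.00218 in AT1G31690. The annotation names no probe set for HSFC1 itself, and the largest rise of any probe set in this line, from 2.13 ± 0.00 to 13.06 ± 0.05, was in a probe set that is unnamed here. In other lines the largest rise of any probe set, also unnamed here, was 9 in DEAR1, 7.88 in CRF3, 6.32 in ZF, 6.04 in CZF1, 4.39 in RAV1 and 4.24 in MYB44 (limma adjusted p up to 2.31e-05), and in CRF2 and MYB73 the largest differences were 1.85 and 2.39 and did not pass (adjusted p = 0.767 and 1). In ERF5 the largest was 5.57, in AT4G33720, and did not pass either (adjusted p = 0.168). Whether any of these belongs to an overexpressed factor is not known here.

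Of 12 heat shock and protein folding genes, 4 rose and 1 fell (camera adjusted p = 0.0018, and adjusted p = 0.551 with an estimated correlation). Besides ATHSP22.0 the risers were HSA32, needed for acquired thermotolerance (4.58 ± 0.19, adjusted p = 2.8e-12), and the co-chaperones Hop3 (4.02 ± 0.26, adjusted p = 2.26e-09) and Hop2 (1.1 ± 0.20, adjusted p = 0.00103), while the chaperone gene Hsp70-2 changed by -1.59 (adjusted p = 0.00543). Of 9 ATG8 autophagy genes 4 rose, ATG8H (1.5), ATG8G (1.23), APG8A (1.21) and APG8H (0.81), with a list camera adjusted p = 0.00243 and adjusted p = 0.551 with an estimated correlation. The HSFC1 arrays had GAPDH differences between 3' and 5' probe sets of 1.63 and 1.78, and ubiquitin differences of 1.66 and 1.71, all above those of the control. In the fixed list of flavonoid and anthocyanin synthesis, 3 of 4 members fell, or 4 when adjusted over the list alone, with a median of -2.37 (camera adjusted p = 0.0241, and adjusted p = 0.893 with an estimated correlation). These were the glycosyltransferases AT4G14090 (-2.70, adjusted p = 0.0254) and UF3GT (-2.29, adjusted p = 0.0454) and the acyltransferase AT5MAT (-1.46, adjusted p = 0.0224), and DFR was at -2.45 (adjusted p = 0.0627). A wider list holding those genes, made from the annotation's names, had 4 of 10 members lower, UGT78D2 being the other (camera adjusted p = 0.0141, and adjusted p = 0.893 with an estimated correlation). Among nuclear photosynthesis genes 3 of 32 fell, CaS (-1.52), HEME1 (-1.06) and HEMB1 (-0.86), with a list camera adjusted p = 0.0141 and adjusted p = 0.898 with an estimated correlation. Without the filter on signal the 4 anthocyanin genes and 3 photosynthesis genes that fell, and APG8A, lost their calls, and against the WT of the cold experiment ATG8G, APG8A and APG8H lost theirs. AT4G14090, UF3GT, AT5MAT, CaS, HEME1, HEMB1 and APG8A also lost their calls without either control array or HSFC1 replicate 1 (adjusted p up to 0.464 in UF3GT), UGT78D2 in all 4 fits with an array left out, APG8H in 3 and ATG8G in 2, and AT1G31690 without HSFC1 replicate 1 (adjusted p = 0.0698).

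Among the cold-regulated genes in HSFC1, LTI30 rose by 2.19 ± 0.45 (adjusted p = 0.00294), COR15A by 1.80 ± 0.45 (adjusted p = 0.0121) and COR47 by 1.79 ± 0.57 (adjusted p = 0.0483), and COR15B was at 0.02 ± 0.47 (adjusted p = 0.994). The CBF regulon list did not pass (camera adjusted p = 0.0628), with 3 of 4 higher also when adjusted over the list alone. Against the WT of the cold experiment, which had the higher COR15A level of the WT groups, the COR15A call was lost and COR15B stood at -1.81. COR47 lost its call without the filter and with any 1 of the 4 arrays left out (adjusted p 0.075 to 0.306), COR15A without control replicate 2 or HSFC1 replicate 1 (adjusted p up to 0.12). In all, 1060 probe sets rose and 824 fell, 1247 of them at least 2-fold. The share higher was 56.3%, but with the WT of the cold experiment as control 1253 were higher and 5960 lower, and with all 4 WT arrays 26.2% of 4888 were higher. With the spread estimated without the CRF3 arrays 3126 were changed, and 1238 with only the groups compared. There were 858 and 974 changed without control replicate 1 or 2, 778 without HSFC1 replicate 1 and 1725 without HSFC1 replicate 2, and 14 of the 27 named genes past the threshold kept their call in each of these fits, among them the 5 genes that rose from near the floor, LTI30, HSA32, Hop2, Hop3 and ATG8H.

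**Figure D2:**
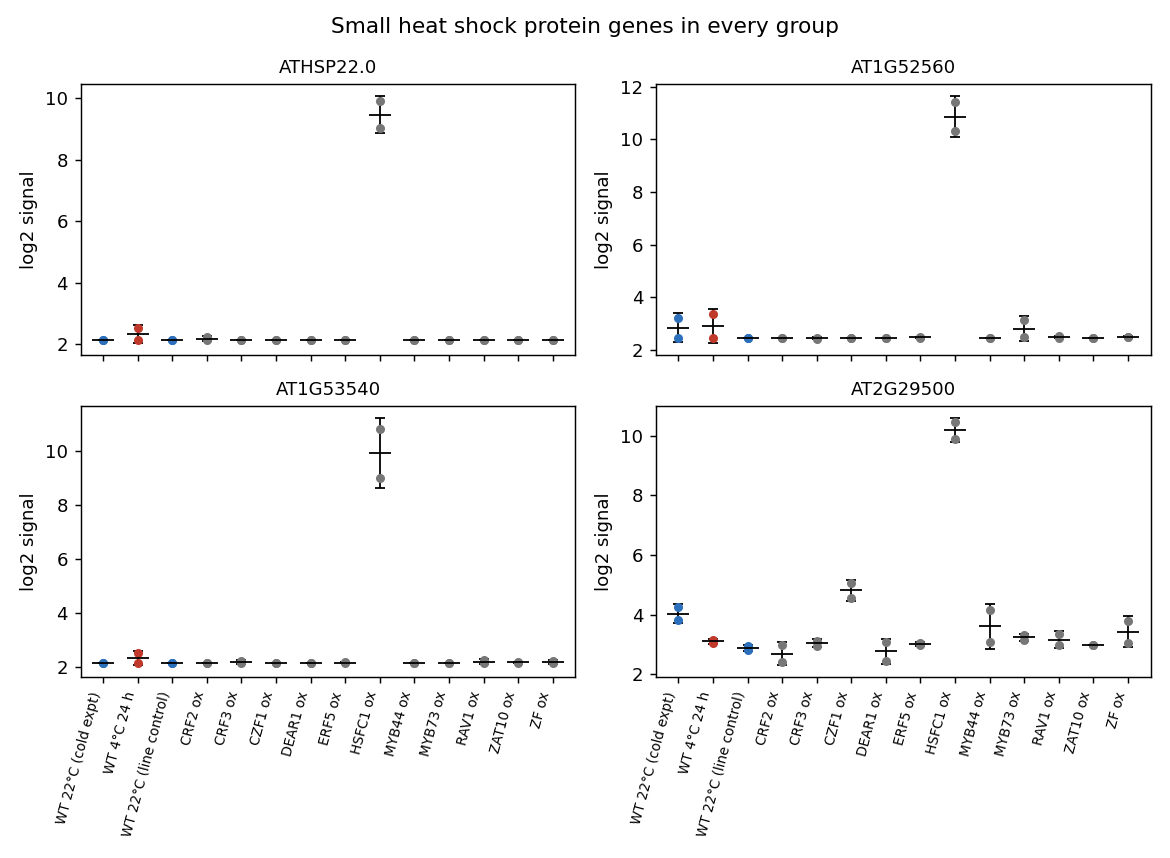
Log2 signal (vertical axis) of the heat shock genes named for HSFC1 in each of the 14 groups (horizontal axis), with points for arrays (WT at 22°C blue, WT at 4°C red, lines grey), horizontal marks for group means and error bars for the SD. In HSFC1 the group mean of ATHSP22.0 was 9.46, against 2.14 in the WT control of the lines.

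The ZAT10 line gave the one direct check of a transgene. ZAT10 (STZ), a C2H2 zinc finger factor, stood at 12.94 ± 0.02 in this line and at 4.08 ± 0.01 in the control (change 8.86 ± 0.70, adjusted p = 1.3e-06), and no other group had a mean above 6.6. CYP71B22 (AT3G26200), a cytochrome P450, rose by 2.54 ± 0.45 (adjusted p = 0.00313). AT5G57760, AT2G43590, AT3G51660 and AT2G04460 rose by 3.1, 3.08, 3.05 and 2.94. AT4G19430 changed by -5.11 ± 0.91 (adjusted p = 0.00316), the C2H2 zinc finger gene AT2G28200 by -2.68 ± 0.33 (adjusted p = 0.00014), the antenna protein gene LHCB4.3 (AT2G40100) by -2.51 ± 0.55 (adjusted p = 0.0127), and AT4G28706 and AT2G32160 by -2.54 and -2.47. COR15A fell from 7.04 ± 0.32 to 5.42 ± 0.02 (change -1.61 ± 0.45, adjusted p = 0.0473), a call lost without the filter on signal and when any 1 of the 4 arrays was left out (adjusted p 0.126 to 0.319).

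Of 12 unfolded protein response genes in ZAT10, 1 passed, DER2.1 (0.74, adjusted p = 0.0466), with a list median of 0.36 (camera adjusted p = 0.035, and adjusted p = 0.893 with an estimated correlation). The ATG8 list in ZAT10 had a median of 0.55 with 0 of 9 members past limma's threshold (camera adjusted p = 0.0141, and adjusted p = 0.633 with an estimated correlation), and the wider anthocyanin list a median of -0.54 with 0 of 10 past it (camera adjusted p = 0.0381, and adjusted p = 0.893 with an estimated correlation). Over all tested probe sets 403 rose and 338 fell, a share of 54.4% higher that became 39.7% after quantile normalization, 15.4% of 4670 against the WT of the cold experiment and 24.1% of 2186 against all 4 WT arrays. With the spread estimated without the CRF3 arrays there were 1718. The ZAT10 arrays had GAPDH differences between 3' and 5' probe sets of 1.48 and 0.99 and ubiquitin differences of 1.53 and 1.3. The count was 139 and 222 without control replicate 1 or 2, and 199 and 227 without ZAT10 replicate 1 or 2. AT2G43590, AT3G51660 and DER2.1 lost their calls against the WT of the cold experiment, and 7 of the 13 named genes past the threshold kept theirs whichever array was left out. AT3G51660, LHCB4.3, AT2G32160, DER2.1 and COR15A lost theirs in all 4 of these fits and CYP71B22 in 1.

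In the ZF line AT2G43535, which encodes a small cysteine-rich protein, went from 6.17 ± 0.24 to 10.16 ± 0.08 (change 4.00 ± 0.48, adjusted p = 0.000255), and the defensin gene PDF2.1 (AT2G02120) rose by 3.04 ± 0.65 (adjusted p = 0.00867). AT2G16005 rose by 4.53, AT2G43590 by 2.35 and AT1G47400 by 2.30. PR-1-LIKE (AT2G19990) and AT2G19970, both of the pathogenesis-related protein 1 family, changed by -3.27 ± 0.73 and -2.93 ± 0.78 (adjusted p = 0.0113 and 0.0296). The extensin-like gene AT1G26250 changed by -2.76, AT5G14650 by -4.19, and AT1G13650, which had the largest named fall in the cold, by -3.03. Among 8 SWEET sugar transporters 2 fell, SWEET2 (-1.77, adjusted p = 0.00449) and SWEET16 (-1.08, adjusted p = 0.0124), with a list camera adjusted p = 0.0095 and adjusted p = 0.893 with an estimated correlation. COR15A was at 1.23 ± 0.45 (adjusted p = 0.106) and COR47 at -0.31 (adjusted p = 0.832), and of the CBF regulon list 2 of 4 were higher when adjusted over the list alone. In total 783 probe sets rose and 350 fell, 69.1% higher and 53.0% after quantile normalization, 14.8% of 4592 against the WT of the cold experiment and 29.2% of 2208 against all 4 WT arrays. The ubiquitin difference between 3' and 5' probe sets was 1.47 and 1.69 in the ZF arrays. Their 25S ribosomal RNA signal was 11.77 and 10.9, against 10.23 and 10.13 in the control. There were 2355 changed with the spread estimated without the CRF3 arrays, 200 and 314 without control replicate 1 or 2, and 385 and 312 without ZF replicate 1 or 2. Against the WT of the cold experiment AT2G43590 was at -0.06 and PDF2.1, AT1G47400, AT5G14650, PR-1-LIKE and AT2G19970 lost their calls, as AT1G47400, AT1G13650 and AT2G19970 did without the filter, and 4 of the 12 named genes past the threshold (AT2G16005, AT2G43535, AT2G43590 and AT1G26250) kept their call whichever array was left out.

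In the MYB44 line, the glutaredoxin genes AT4G15680 and AT2G30540 rose by 2.80 ± 0.28 and 2.38 ± 0.35 (adjusted p = 6.6e-05 and 0.00192). AT2G43590, AT1G52100, a jacalin-related lectin, and AT2G39920 rose by 2.17, 2.08 and 2.02. The expansin EXPB1 changed by -2.78 ± 0.43 (adjusted p = 0.00291), the extensin-like AT1G26250 by -2.99 ± 0.48 (adjusted p = 0.00358) and AT5G14650, of the pectin lyase superfamily, by -4.15 ± 0.90 (adjusted p = 0.0239). AT5G37690, of the GDSL lipases, changed by -3.54 ± 0.46 (adjusted p = 0.000461), the lipid transfer protein gene AT4G12490 by -3.56 and AT4G38080 by -2.84. Of 22 expansins and xyloglucan hydrolases, EXPB1 alone passed, with a list median of -0.63 (camera adjusted p = 4.83e-05, and adjusted p = 0.893 with an estimated correlation). The CBF regulon list had a median of -1.05 with 0 of 4 members past limma's threshold and 2 lower when adjusted over the list alone (camera adjusted p = 0.0156, and adjusted p = 0.893 with an estimated correlation). The late embryogenesis abundant list had a median of -0.89 with 0 of 6 past it (camera adjusted p = 0.0326, and adjusted p = 0.893 with an estimated correlation). The MYB44 arrays had GAPDH differences between 3' and 5' probe sets of 1.43 and 1.31 and ubiquitin differences of 1.51 and 1.43. Altogether 140 probe sets rose and 129 fell. The share higher was 52.0%, 10.6% of 3360 against the WT of the cold experiment and 23.8% of 660 against all 4 WT arrays. There were 975 changed with the spread estimated without the CRF3 arrays, and limma called 0 with only the groups compared, against 2318 at an unadjusted p under 0.05 with all arrays. The count was 36 and 33 without control replicate 1 or 2, 188 without MYB44 replicate 1 and 78 without MYB44 replicate 2. Against the WT of the cold experiment AT2G43590 and AT2G39920 were at -0.24 and -0.21 and AT1G52100 and AT5G14650 lost their calls, as these did without the filter with AT4G12490 and AT4G38080, and 4 of the 11 named genes past the threshold (AT4G15680, AT2G30540, AT5G37690 and EXPB1) kept their call whichever array was left out.

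The CRF3 line, overexpressing a cytokinin response factor, had replicates that differed more than those of any other group. Across probe sets its 2 arrays correlated at r = 0.883 (across probe sets, which are not independent replicates), and their root mean square SD was 0.707 against 0.181 to 0.382 in the other groups. CHI (AT2G43570), a chitinase gene, was at 7.80 ± 4.08 against 3.66 ± 0.15 (adjusted p = 0.0406), ZAT10 (STZ) at 6.6 ± 2.62 against 4.08 ± 0.01 (adjusted p = 0.0367), and AT5G39850, AT5G39520 and AT2G43660 rose by 2.75, 2.72 and 2.64. AT1G62510, AT5G62210, AT1G13650, the photosystem II gene psbB and AT1G23205 changed by -3.04, -2.96, -2.58, -2.29 and -2.28. All 28 named genes past the threshold lost their call without CRF3 replicate 2 (adjusted p 0.0724 to 0.844) and 0 of 28 without replicate 1 (limma adjusted p up to 0.0143). Without control replicate 1 or 2, 27 and 26 of them lost it. In all 921 probe sets rose and 447 fell, 67.3% higher and 51.7% after quantile normalization, 14% of 6691 against the WT of the cold experiment and 25.1% of 4846 against all 4 WT arrays. There were 837 changed without the filter, 13 changed without CRF3 replicate 2, 6713 without replicate 1, 6 and 95 without control replicate 1 or 2, and 0 when only these 4 arrays were fitted with limma, against 4735 at an unadjusted p under 0.05 in the fit of all arrays.

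With both CRF3 replicates, 5 of 9 ATG8 genes rose, ATG8B (2.00), ATG8G (1.72) and APG8A (1.32) among them (camera adjusted p = 0.00289, and adjusted p = 0.551 with an estimated correlation). The CRF3 arrays had GAPDH differences between 3' and 5' probe sets of 2.04 and 1.81 and ubiquitin differences of 1.41 and 1.74, and a 25S ribosomal RNA signal of 9.98 in replicate 1 and 11.47 in replicate 2. Chloroplast-encoded genes had 12 of 66 members lower, with a median of -0.79 (camera adjusted p = 6.3e-09, and adjusted p = 0.893 with an estimated correlation), and nuclear photosynthesis genes 4 of 32, NdhN (-1.90), LHCB4.2 (-1.56), HEME1 (-1.28) and TAPX (-1.03), with a list camera adjusted p = 6.82e-09 and adjusted p = 0.893 with an estimated correlation. Of 7 tubulins 2 fell, TUB1 (-1.24) and TUA1 (-1.08), with a list camera adjusted p = 0.00332 and adjusted p = 0.893 with an estimated correlation. Of 22 expansins and xyloglucan hydrolases 2 fell, EXPB1 (-1.80) and EXLA1 (-1.54, but 0.84 against the WT of the cold experiment), with a list camera adjusted p = 0.00214 and adjusted p = 0.893 with an estimated correlation. Family 1 glycosyltransferases had 3 of 33 members lower, UGT88A1 (-1.16), UGT76E11 (-0.85) and UGT76C2 (-0.82), with a list camera adjusted p = 0.0418 and adjusted p = 0.633 with an estimated correlation. The wider anthocyanin list had a median of -0.73 with 0 of 10 past limma's threshold (camera adjusted p = 0.0441, and adjusted p = 0.893 with an estimated correlation). COR47 and COR15A were at -1.54 (adjusted p = 0.0869) and -0.75 (adjusted p = 0.269). The named members of these lists also lost their calls without CRF3 replicate 2.

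The CZF1 line, overexpressing a CCCH zinc finger factor, had arrays whose median over tested probe sets, 7.03 and 7.04, lay with the 7.0 to 7.04 of the cold experiment and apart from the 6.47 to 6.66 of the other 22 arrays. For that reason, and after the array medians had been seen, CZF1 is described first against the WT of the cold experiment and then against its labelled control. Against the former, EXLA1 (AT3G45970), an expansin-like gene, rose from 6.37 ± 0.27 to 9.78 ± 0.49 (change 3.41 ± 0.36, adjusted p = 1e-04), the thionin THI2.2 (AT5G36910) by 2.62 ± 0.37 (adjusted p = 0.00119), COR27 by 2.51 ± 0.42 (adjusted p = 0.00493), the lectin AT1G52100 by 3.22 and AT1G70270 by 3.18. AT1G73040, AT5G66340, AT1G80130, AT3G03440 and AT1G62840 changed by -1.94, -1.62, -1.46, -1.19 and -1.14. COR15A, COR15B and COR47 were at -0.24, -0.15 and 0.08 (adjusted p = 0.945, 0.977 and 1), and LTI30 was at 1.24 ± 0.45 (adjusted p = 0.234). Of 33 family 1 glycosyltransferases 1 rose, UGT85A2 (1.14, adjusted p = 0.00748), with a list median of 0.34 (camera adjusted p = 0.0381, and adjusted p = 0.633 with an estimated correlation). This comparison called 126 probe sets higher and 39 lower, or 84 and 97 changed without replicate 1 or 2 of that WT, 44 without CZF1 replicate 1 and 217 without CZF1 replicate 2. Of the 10 largest changes named, 5 kept their call in each of these fits. COR27 lost it without CZF1 replicate 1 or WT replicate 1, AT1G73040 without CZF1 replicate 1 or WT replicate 2, AT1G62840 and AT3G03440 in each fit but that without CZF1 replicate 2, and AT1G80130 in every one (adjusted p up to 0.312).

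Against its labelled control, the chitinase-family gene AT2G43590 in CZF1 rose by 4.50 ± 0.39 (adjusted p = 4.04e-07), AT1G52100 by 4.13 ± 0.49 (adjusted p = 1.52e-05), and AT1G07050, AT2G39920 and AT5G55450 by 3.91, 3.76 and 3.66. AT3G04990, AT3G43640, AT2G23500, AT5G58750 and AT1G68420 changed by -4.99, -4.70, -4.54, -4.51 and -4.39. COR15B and COR15A rose by 1.69 and 1.32 (limma adjusted p = 0.0108 and 0.0294), calls lost for COR15A with any 1 of the 4 arrays left out (adjusted p 0.0622 to 0.165) and for COR15B without control replicate 2 or CZF1 replicate 1 (up to 0.0987). LTI30 rose by 1.28 ± 0.45 (adjusted p = 0.0343), a call lost without the filter, after quantile normalization, with any 1 of the 4 arrays left out (adjusted p 0.0813 to 0.152) and against the other WT, where it had the same sign. COR15B and COR15A were opposite in sign to the values against the other WT, as were AT2G23500 (0.27) and AT1G68420 (0.45). The 10 largest changes kept their calls whichever array was left out. The other named genes of this comparison except AT2G43590 and AT1G52100 were not called against the other WT. In all 5164 probe sets rose and 613 fell, with a median over all tested probe sets of 0.43. The share higher was 89.4%, and 48.1% of the 2299 changed after quantile normalization. There were 2953 and 3453 changed without control replicate 1 or 2, 2911 without CZF1 replicate 1, and 1889 with all 4 WT arrays at 22°C as control.

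In the DEAR1 line 19 probe sets rose and 21 fell. AT1G52820 rose from 2.16 ± 0.02, near the floor, to 5.58 ± 0.59 (adjusted p = 1.33e-06), AT2G43590 by 2.38 ± 0.39 (adjusted p = 0.0125), AT2G39920 by 2.01, AT1G56300 by 1.69 and CCL (AT3G26740) by 1.5. AT5G44530 changed by -2.74 ± 0.51 (adjusted p = 0.0265), AT3G19370 by -2.17, TBL28 (AT2G40150) by -1.74, the zinc finger gene AT2G28200 by -1.67 and AT1G17620 by -1.58. COR47 was at -2.65 ± 0.57 (adjusted p = 0.0562), and 2 of 4 CBF regulon genes were lower when adjusted over the list alone. The CYP71B cytochromes P450 had a median of 0.52 with 0 of 13 past limma's threshold (camera adjusted p = 0.0141, and adjusted p = 0.633 with an estimated correlation). Expansins and xyloglucan hydrolases had a median of -0.29 with 0 of 22 past it (camera adjusted p = 0.0381, and adjusted p = 0.893 with an estimated correlation). At an unadjusted p under 0.05 there were 1490 probe sets. The number changed was 395 with the spread estimated without the CRF3 arrays, 64 without the filter, 83 after quantile normalization and 0 with limma on only the groups compared. It was 5363 against the WT of the cold experiment (10.3% higher, against 47.5%) and 1287 against all 4 WT arrays (19.4% higher). The DEAR1 arrays had ubiquitin differences between 3' and 5' probe sets of 1.56 and 1.78. Only AT1G52820 among 10 named genes kept its call whichever array was left out, with 5 and 2 probe sets changed without control replicate 1 or 2, 26 without DEAR1 replicate 1 and 276 without DEAR1 replicate 2, and AT2G43590 and AT2G39920 were at -0.03 and -0.22 against the other WT, where AT1G56300, CCL and AT2G28200 lost their calls. Without the filter 7 of the 10 lost theirs, AT1G52820, AT2G43590 and CCL being the others.

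In the ERF5 line 11 probe sets rose and 2 fell, and 1442 had an unadjusted p under 0.05. AT2G43590 rose from 4.82 ± 0.30 to 7.67 ± 0.01 (adjusted p = 0.0129), AT4G36500 by 1.96 ± 0.32 (adjusted p = 0.0271), AT1G55450 by 1.43, AT1G25275 by 1.13 and AT5G52450 by 0.97, the last at -0.29 against the WT of the cold experiment, where the other risers lost their calls. EXO (AT4G08950), a gene induced by brassinosteroids, changed by -1.28 ± 0.22 (adjusted p = 0.0339). The fixed flavonoid and anthocyanin list had a median of -1.11 with 0 of 4 past limma's threshold and 1 lower when adjusted over the list alone (camera adjusted p = 0.0441, and adjusted p = 0.893 with an estimated correlation). The ATG8 genes had a median of 0.45 with 0 of 9 past it (camera adjusted p = 0.00932, and adjusted p = 0.633 with an estimated correlation). The ubiquitin difference between 3' and 5' probe sets was 1.61 and 1.52 in the ERF5 arrays. The share higher was 84.6%, 68.4% after quantile normalization, 13.7% of 5991 against the WT of the cold experiment and 18.3% of 2206 against all 4 WT arrays. There were 190 changed with the spread estimated without the CRF3 arrays, 74 without the filter and 0 with limma on only the groups compared. With 1 array left out in turn, AT2G43590 and AT4G36500 lost their calls in 3 of 4 fits (adjusted p up to 0.127 and 0.293) and the other 4 named genes in all 4 (up to 0.445), limma calling 0 probe sets without control replicate 1 or 2 or ERF5 replicate 2 and 14 without ERF5 replicate 1.

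For CRF2 and MYB73, limma called 0 probe sets, with 985 and 448 at an unadjusted p under 0.05. For RAV1 it called 1, an unnamed probe set that rose from 5.94 ± 0.25 to 10.32 ± 0.93 (adjusted p = 2.31e-05), with 734 at an unadjusted p under 0.05. COR15A was at -0.99 ± 0.45 in CRF2 (adjusted p = 0.782), -0.26 ± 0.45 in MYB73 (adjusted p = 1) and -0.13 ± 0.45 in RAV1 (adjusted p = 1). In MYB73 the chloroplast-encoded genes had a median of -0.24 with 0 of 66 past limma's threshold (camera adjusted p = 1.81e-09, and adjusted p = 0.893 with an estimated correlation). The 25S ribosomal RNA signal was 10.68 and 10.58 in the MYB73 arrays, against 10.23 and 10.13 in the control. With the spread estimated without the CRF3 arrays limma called 14 in CRF2 and 6 in RAV1, and without the filter 24 in CRF2, 8 in MYB73 and 11 in RAV1. Against the WT of the cold experiment 5278, 4792 and 3954 were changed in CRF2, MYB73 and RAV1, of which 13.2%, 11.9% and 13.7% were higher. The WT groups themselves differed in 5397 probe sets, so these counts carry that difference and are not read as effects of the lines. Leaving out CRF2 replicate 2 gave 4 probe sets, MYB73 replicate 1 gave 3 and RAV1 replicate 2 gave 3. In simulated data for RAV1, 44% of probe sets changed by 1 on the log2 scale and 90% of those changed by 2 were recovered.

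**Figure D3:**
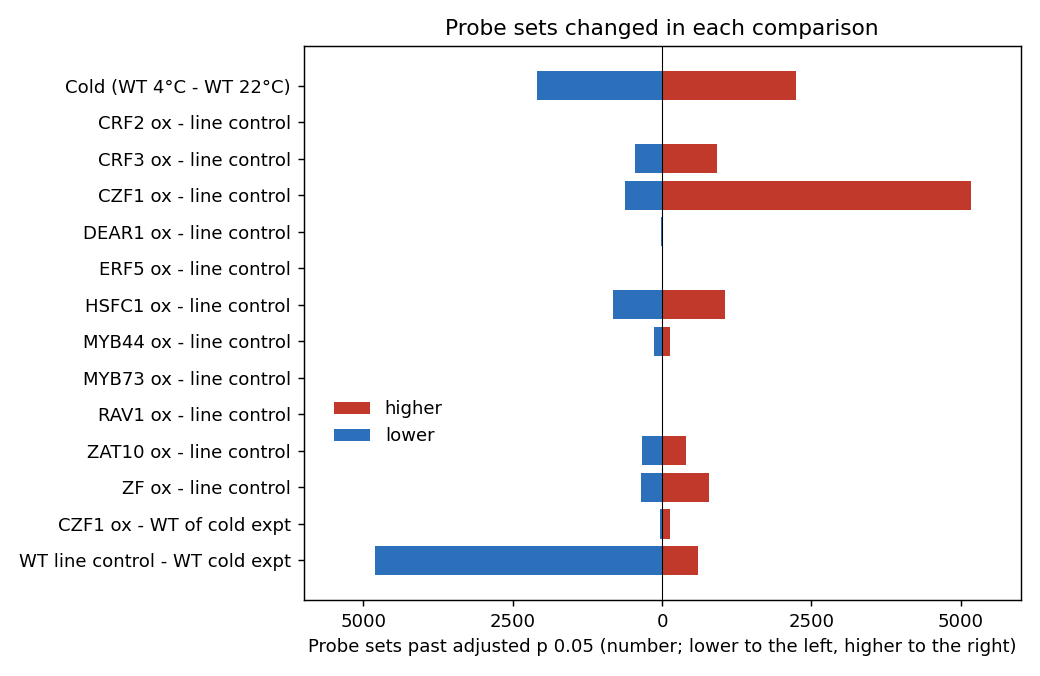
Number of probe sets (horizontal axis) higher (red, to the right) and lower (blue, to the left) at limma's adjusted p under 0.05 in each comparison (vertical axis), the first group of each pair relative to the second. CZF1 against its labelled control had the most, 5164 higher and 613 lower, and the bars of DEAR1, ERF5 and RAV1 are too short to read at this scale.

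The series title describes the factors as induced by cold, so the calls of each line were set against those of the cold response, which shared no array with them. In HSFC1, 224 probe sets were higher in both, where independent lists of these sizes would share 149.0 (odds ratio 1.71, Fisher's exact test, adjusted p = 5.29e-10), and 216 lower in both against 108 (odds ratio 2.50, adjusted p = 1.16e-23). ZF shared 186 higher against 110 (odds ratio 1.99, adjusted p = 6.17e-13) and 100 lower against 46.0 (odds ratio 2.73, adjusted p = 1.08e-13). CRF3 shared 229 higher against 130 and 97 lower against 58.7 (adjusted p = 2.74e-18 and 1.63e-06), but without its replicate 2 only 9 probe sets were called higher and 4 lower, of which 5 and 0 were shared, too few to test the lower overlap (odds ratio 7.65 for higher, Fisher's exact test, unadjusted p = 0.00421). ZAT10 shared 76 higher against 56.7 (adjusted p = 0.0179, a call lost against the other WT at an odds ratio of 1.16, where both comparisons used the same WT arrays) and 77 lower against 44.4 (adjusted p = 3.32e-06), and 77 probe sets were higher in ZAT10 and lower in the cold against 52.9 (adjusted p = 0.00172). For MYB44 the overlaps in the same direction did not pass (26 higher against 19.7 and 23 lower against 16.9, adjusted p = 0.308 and 0.278), though the lower overlap passed with a 2-fold threshold (odds ratio 2.1, unadjusted p = 0.013) and with the spread estimated without the CRF3 arrays (odds ratio 1.45, unadjusted p = 0.0017), while 35 were higher in MYB44 and lower in the cold against 18.4 (adjusted p = 0.000476). CZF1 against its labelled control shared 987 higher against 726 (adjusted p = 8.16e-34) and 73 lower against 80.5 (adjusted p = 0.674), with 734 higher in CZF1 and lower in the cold against 678 (adjusted p = 0.0155) and 56 the other way against 86.2 (adjusted p = 0.000782). Of the probe sets called in both, 80.3% went the same way in CRF3, 68.3% in HSFC1, 67.6% in ZF, 57.3% in CZF1, 56.9% in ZAT10 and 50% in MYB44. Probe sets are not independent, so these p-values describe overlap on these arrays.

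CZF1 against the WT of the cold experiment shared 62 probe sets higher with the cold against 17.7 and 14 lower against 5.12 (adjusted p = 6.32e-20 and 0.000845), but these comparisons used the same WT arrays. Unchanged groups simulated with those shared arrays gave a correlation of 0.500 and a covariance of 0.0448, and the observed values across probe sets were 0.220 and 0.0715. Part of that overlap may come from the shared control arrays.

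Pairs of lines with CRF, MYB or zinc finger factors were compared over all tested probe sets. The zinc finger is of the C2H2 class in ZAT10 and the CCCH class in CZF1. Each line was set against the same 2 control arrays, for which unchanged groups gave a simulated covariance of 0.0448. That value used the spread of all groups, CRF3 included, and may be too high for these control arrays. The correlation across probe sets was 0.453 for CRF2 and CRF3, 0.255 for MYB44 and MYB73, 0.286 for ZAT10 and CZF1 and 0.501 for ZF and CZF1. None lay clearly above the 0.500 simulated for unchanged groups. The covariance was 0.0822 for CRF2 and CRF3, 0.0305 for MYB44 and MYB73, 0.0927 for ZAT10 and CZF1 and 0.173 for ZF and CZF1. With the second line of each pair set against the WT of the cold experiment, so that no array was shared, the values were 0.0751, -0.107, 0.0273 and 0.0614. That WT differed from the lines' control in 5397 probe sets. For CRF3 and MYB73, whose array medians lay with the lines' control, the values therefore also carry the difference between the WT groups. Without CRF3 replicate 2 the covariance of CRF2 and CRF3 was 0.0475. ZF and CZF1 had 619 probe sets higher in both, where independent lists would share 254, and 64 lower in both against 13.5. ZAT10 and CZF1 had 270 higher against 131 and 19 lower against 13.0. Called in opposite directions were 31 probe sets in ZF and CZF1 and 110 in ZAT10 and CZF1. Part of these overlaps may come from the shared controls.

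The WT groups at 22°C were compared with each other to measure how far the cold experiment and the lines' control differed. COR15B and COR15A were lower in the lines' control, at 7.26 ± 0.13 against 9.10 ± 0.04 and 7.04 ± 0.32 against 8.59 ± 0.21 (changes -1.84 and -1.56, adjusted p = 0.00772 and 0.0145), calls that were lost after quantile normalization, as was that of AT1G12030. COR15A also lost its call without replicate 2 of either group (adjusted p up to 0.102), COR15B without replicate 2 of the lines' control (0.0517), and AT1G12030 in 3 of the 4 fits with an array left out. AT2G22340, AT1G68420, AT2G23500, AT3G04990 and AT3G43640 were higher there by 4.96, 4.84, 4.81, 4.59 and 4.50, and AT4G01390, AT1G80130, AT5G55450, AT3G01960 and AT1G12030 were at -3.74, -3.34, -3.30, -2.57 and -2.43. Altogether 595 probe sets were higher and 4802 lower in the lines' control, with a median of -0.42 over all tested probe sets. The share higher was 11%, and 53.4% of the 1660 changed after quantile normalization. Values and counts of the lines other than CZF1 against the WT of the cold experiment carry this difference as well. There were 3104 and 2857 changed without replicate 1 or 2 of the cold experiment's WT, and 2435 and 2816 without replicate 1 or 2 of the lines' control.

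**Figure D4:**
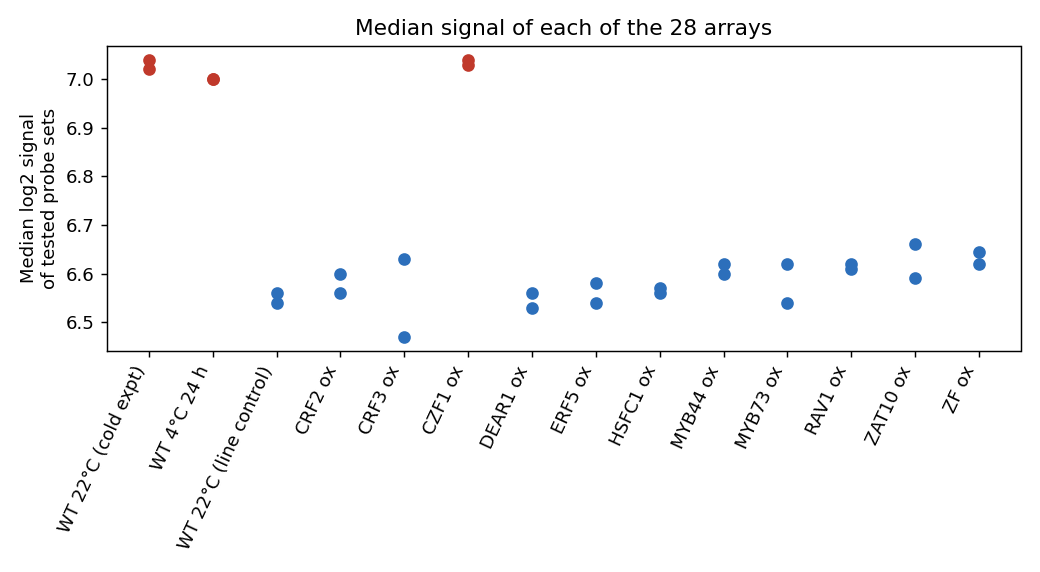
Median log2 signal over tested probe sets (vertical axis) of each of the 28 arrays by group (horizontal axis), with 1 point per array and the cold experiment and CZF1 in red. The red points lie between 7.0 and 7.04 and the blue points between 6.47 and 6.66.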

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

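All the tests of explanations in this part were chosen after the results they bear on had been seen, and the test of degraded RNA and the bound for the last test were changed after their values were known.

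Control probe sets of the arrays, which were left out of the limma tests above, were compared with their levels in the 4 WT arrays at 22°C. Of 48 pairs of a group and a measure, 12 had both arrays above all 4 WT arrays, where chance would give 3.2 if all arrays were exchangeable. The pairs are not independent, since all 12 groups were set against the same 4 WT arrays, which come from different sets, and 7 of the 12 were of ubiquitin and 5 of 25S ribosomal RNA. The difference between the 3' and 5' ubiquitin probe sets (WT mean 1.22, SD 0.11, highest 1.33) was 1.61 in CRF2, 1.58 in CRF3, 1.67 in DEAR1, 1.56 in ERF5, 1.68 in HSFC1, 1.47 in MYB44 and 1.58 in ZF. The 25S ribosomal RNA signal (WT mean 9.96, SD 0.26, highest 10.23) was 10.62 in CZF1, 10.63 in MYB73, 10.70 in RAV1, 10.80 in ZAT10 and 11.34 in ZF. Only values above the WT arrays were counted. The 25S signal went the other way in DEAR1 (9.06 and 8.96) and ERF5 (8.8 and 9), below the lowest of the 4 WT arrays (9.73).

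CZF1 differed from its labelled control in 5777 probe sets. Whether overexpression of the factor was the whole cause was not decided by the share called the same way against the WT of the cold experiment, 1.92% (111). That comparison called 165 probe sets in all, so the share could only be small whatever the cause. The count of 165 beside 5777 shows that most calls depended on which WT was the control. A change of intensity scale is argued against as the whole cause, since 2299 probe sets were called after quantile normalization, 1686 of them among those 5777. A difference between the sets of arrays may account for much of it. Of the calls, 68.7% (3967) were called the same way in the WT of the cold experiment against the same control. That share was taken before quantile normalization, so it cannot tell a difference of scale from one of another kind. After quantile normalization the WT groups still differed in 1660 probe sets. The shared control arrays add to the share by an amount not measured here. In 50 simulations with an unchanged WT the highest share was 0.0151%. That WT had 0.06 calls on average, and so almost no calls to share, so this cannot give the amount. Whether such a difference came from array handling or from separate growth was not tested.

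CRF3 replicate 2 stood apart from every other array, with a correlation of 0.883 with its own replicate. Degraded RNA stays open, since the test could not decide it. In replicate 2, 2 of the 3 differences between 3' and 5' probe sets lay above both control arrays (GAPDH 1.81 and ubiquitin 1.74) and actin did not (5.36). Replicate 1 also lay above them in GAPDH (2.04) and ubiquitin (1.41), as did both arrays of 10 and 8 of the 11 lines. Replicate 2 lay within the ranges of the other arrays (0.75 to 2.04, 1.08 to 1.78 and 4.76 to 6.01), so these measures did not set it apart. An array of another line or of WT is argued against, since the unnamed probe set that marked replicate 1 most (at 9.15) was at 11.53 in replicate 2, higher by 7.81 than in any array of another group. Root tissue in the harvest is argued against, since the median of the 3 root markers was at -1.17 relative to the WT control. EXPA7 and EXPA18 were each at -1.17 and the most abundant, PYK10, at -0.58. The first 2 are expansins, whose list was called lower in CRF3 with camera's preset correlation, so only PYK10 stands apart from that change. What else may have set this array apart stays open, and no biological explanation was tested.

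Leaving CZF1 aside, 45 probe sets were called the same way in at least 4 of 10 lines, a threshold chosen after seeing the data, with 28 higher and 17 lower. The lines' control arrays may stand apart from the other WT here, since after quantile normalization the WT of the cold experiment lay on the lines' side of the control in 97.8% of them (44). An effect common to overexpressing lines cannot be told apart from this, since the WT of the cold experiment lay nearer to the control than to the lines in 24.4% (11, exact 95% interval 12.9 to 39.5) and belongs to another set of arrays. The bound for that test was first a share of at most 25%, and was changed to an interval below 25% once 24.4% was known, because the value lay within its error of the bound.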

How the results depend on the processing

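The fit without the CRF3 arrays was chosen after seeing the data, as were the overlap and covariance of CRF3 without each of its replicates and the fits of CZF1 against the WT of the cold experiment without each array. Except where a reason is given, the cause of a change was not tested. All 13 counts stayed within 1.5 times with a filter at 6 and with a trended and robust prior, and all named genes kept their direction and call with that prior. Named genes lost 47 calls without the filter, 69 with only the groups compared (2 residual degrees of freedom in place of 14), 9 after quantile normalization, 31 with the replicate number as a block, 33 against the WT of the cold experiment (where 12 directions turned), 15 with all 4 WT arrays as control, and 267 over the fits with 1 array left out, which have fewer arrays. The 33 calls lost against the WT of the cold experiment are those that kept their direction, and the 12 directions that turned are counted apart from them. Of the 29 gene lists called, 0 kept their call in limma's camera with an estimated correlation and 10 kept it with fry. Signals near the floor of 2.13 limit what the changes from it can show.

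With 1 array left out, the counts of changed probe sets were 2799 to 2863 for cold, 0 to 4 for CRF2, 6 to 6713 for CRF3, 2911 to 4053 for CZF1 (44 to 217 against the WT of the cold experiment), 2 to 276 for DEAR1, 0 to 14 for ERF5, 778 to 1725 for HSFC1, 33 to 188 for MYB44, 0 to 3 for MYB73, 1 to 3 for RAV1, 139 to 227 for ZAT10, 200 to 385 for ZF and 2435 to 3104 for the WT groups. The extremes for CRF3 came without control replicate 1 and without its own replicate 1. Where limma called 0, the unadjusted counts with all arrays were 985 for CRF2, 448 for MYB73 and 1442 for ERF5. Without CRF3 replicate 2 the odds ratio of its lower overlap with cold was 0, from 4 probe sets lower in CRF3, too few to test, and that of its higher overlap 7.65, from 9. The covariance of CRF2 and CRF3 ran from 0.0475 without CRF3 replicate 2 to 0.117 without replicate 1.

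With the WT of the cold experiment as control, 165 probe sets were changed in CZF1, 5278 in CRF2, 6691 in CRF3, 5363 in DEAR1, 5991 in ERF5, 7213 in HSFC1, 3360 in MYB44, 4792 in MYB73, 3954 in RAV1, 4670 in ZAT10 and 4592 in ZF. With all 4 WT arrays at 22°C the counts were 1136 in CRF2, 4846 in CRF3, 1889 in CZF1, 1287 in DEAR1, 2206 in ERF5, 4888 in HSFC1, 660 in MYB44, 294 in MYB73, 142 in RAV1, 2186 in ZAT10 and 2208 in ZF. With the spread estimated without the CRF3 arrays they were 14 in CRF2, 395 in DEAR1, 190 in ERF5, 3126 in HSFC1, 975 in MYB44, 6 in RAV1, 1718 in ZAT10 and 2355 in ZF. For the lines other than CZF1, the counts with either other control also carry the difference between the WT groups, which was called in 5397 probe sets.

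Without the filter 24 probe sets were changed in CRF2, 837 in CRF3, 64 in DEAR1, 74 in ERF5, 8 in MYB73 and 11 in RAV1. With only the groups compared, limma called 1238 in HSFC1 and 0 in CRF3, DEAR1, ERF5, MYB44 and RAV1, where the unadjusted counts with all arrays were 4735, 1490, 1442, 2318 and 734. Quantile normalization gave 83 in DEAR1, 2299 in CZF1 and 1660 for the WT groups. A threshold of 2-fold, which can only lower a count, left 2340 for cold, 740 in CRF3, 2474 in CZF1, 1247 in HSFC1, 425 in ZAT10, 572 in ZF and 2161 for the WT groups.

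Directions turned against the WT of the cold experiment for AT2G23500 (0.27), AT1G68420 (0.45), COR15B (-0.15) and COR15A (-0.24) in CZF1, AT2G43590 (-0.03) and AT2G39920 (-0.22) in DEAR1, AT5G52450 (-0.29) in ERF5, COR15B (-1.81) in HSFC1, AT2G43590 (-0.24) and AT2G39920 (-0.21) in MYB44, AT2G43590 (-0.06) in ZF and EXLA1 (0.84) in CRF3. Over all tested probe sets the lines' control had a median of -0.42 relative to that WT. The values of -0.03 to -0.29 in DEAR1, ERF5, MYB44 and ZF were smaller than that offset and are not read as falls of these genes. With the second line against that WT, the covariance was -0.107 for MYB44 and MYB73, 0.0273 for ZAT10 and CZF1 and 0.0614 for ZF and CZF1. The value for MYB44 and MYB73 also carries the difference between the WT groups. The odds ratio of the overlap with cold against that WT came to 3.72 for lower in CZF1, 1.4 for lower in DEAR1, 1.54 for lower in MYB44 and 1.16 for higher in ZAT10, and these are not read as overlap, since both comparisons used the same WT arrays. For such a pair unchanged groups gave a covariance of 0.0448, and the observed covariance with cold was 0.0715 in CZF1, 0.0325 in DEAR1, 0.0204 in MYB44 and 0.0488 in ZAT10. Against the labelled control these overlaps passed Fisher's exact test where they had not before, at an odds ratio of 2.1 (unadjusted p = 0.013) for lower in MYB44 with a 2-fold threshold, and without the CRF3 arrays of 1.66 (unadjusted p = 0.00546) for higher in DEAR1 and 1.45 (unadjusted p = 0.0017) for lower in MYB44.

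The replicate numbers did not pair the arrays. Over 66 pairs of groups among the lines and their control, the correlation of deviations of same-numbered arrays ran from -0.352 to 0.175, with a median of 0.0031 and 4 over 0.1, and it was -0.024 in the cold experiment. With the replicate number as a block the counts moved by over 1.5 times to 25 in DEAR1, 4 in ERF5, 2 in RAV1 and 3495 for the WT groups.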

Other observations

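The genes in this part were singled out after their values had been seen. AT2G43590, of the chitinase family, was at 4.82 ± 0.30 (SD, n = 2) in the lines' control and 7.24 ± 0.50 in the WT of the cold experiment. It was at 9.33 ± 0.24 in CZF1, 7.90 ± 0.16 in ZAT10, 7.67 ± 0.01 in ERF5 and 3.70 ± 0.57 in CRF2, and rose in 5 of the 10 lines other than CZF1. AT2G39920 showed a like spread, at 3.90 ± 0.15 in the lines' control and 6.12 ± 0.22 in the other WT, with 7.66 ± 0.68 in CZF1 and 6.48 ± 0.06 in HSFC1. PYK10, a beta-glucosidase abundant in roots, was at 11.58 ± 0.22 in the cold and 13.16 ± 0.11 in CZF1, the lowest and highest of the 14 group means.

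Among genes called the same way in several of the 10 lines other than CZF1, AT4G22460 fell in 6, AT5G55380 fell in 5, and AT4G14270, AT3G63090 and AT1G56300 rose in 5. The transcription factor gene BZIP34 (AT2G42380) fell in 4. These comparisons share their control arrays.

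Beyond the planned pairs, CRF3 and HSFC1 had 123 probe sets lower in both, where independent lists would share 23.1, and ZF and HSFC1 had 159 higher in both against 52.1. These are not all the unplanned pairs that were compared. Their correlations across probe sets, 0.355 and 0.338, lay below the 0.500 simulated for unchanged groups with the shared controls. The covariance was 0.161 for CRF3 and HSFC1 and 0.129 for ZF and HSFC1, against 0.0448 simulated for unchanged groups with the shared controls. With the second line set against the other WT it was 0.0909 and 0.0175, values that also carry the difference between the WT groups. The values for CRF3 rested on its replicate 2, without which 4 probe sets were lower in CRF3, 3 of them also in HSFC1, and the covariance was 0.0442 (a fit chosen after seeing the data).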
